A study of Drosophila melanogaster with 2 samples.

How the data were processed

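Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos collected 0 to 24 h after laying, with sexes mixed. Per the labels, the flies carried a transgene that fused GFP to the C terminus of CG13624, the gene now named REPTOR, and an antibody against GFP was used for the pull-down. REPTOR is a bZIP transcription factor that acts below the TORC1 growth kinase. The series held 2 biological replicates of a single group, which the labels number 1 and 3. Per the labels, chromatin was fragmented by sonication. An experiment was listed as a possible control, and its own data were not analysed here.

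Peak lists were used as deposited, in 8 files, 4 on each of the dm6 and dm3 builds. Per the notes deposited with the files, each replicate was called against a control file, a further list was called on both replicates together, and the optimal list held the calls that passed a threshold on the irreproducible discovery rate (IDR), which measures how well the replicates rank the same calls. The aligner, the peak caller and their versions are not given in the sources used here. The call lists made by the authors for each replicate and for both together each ended at exactly 30000 lines, including calls from background. Each call carried a peak signal computed by the authors' caller, whose scale depends on the reads that entered it, so the signal was used to rank and filter calls within a list and to compare ranks between lists. Each call also carried a deposited −log10 q, which was saturated: 4854 of the 5321 optimal dm6 peaks shared the highest value of 3.99. That column was used only for a count of calls above 2. The third column used, other than signal and q, was the deposited offset of the summit from the peak start.

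Every peak of the optimal list was found among the calls made on both replicates together, and the list was identical to the 5321 calls of that list with the highest signal (5304 on dm3). Read depth per replicate was not given in the files, so precision is expressed only through numbers of peaks. Intervals on shares are exact Clopper-Pearson intervals at 95%, cover counting error only and take peaks as independent. With a single group there was no comparison between conditions, and with 2 replicates no test was made across replicates. Tests across peaks or genes describe this peak list.

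Coordinates are 1-based and on dm6 unless stated. The largest dm6 peak end on each arm lay inside the Release 6 reference used here, on which sequences were read, and gene models came from the Ensembl annotation of that assembly, without transposable elements. It held 13945 protein-coding genes on arms 2L, 2R, 3L, 3R, X and 4, and 23694 distinct transcription start sites (TSSs) of all gene kinds. The dm3 lists were compared only by number, arm and replicate, since no dm3 annotation was used here. A summit was placed in 1 class, in the order promoter (within 1000 bp of any TSS), 5′ UTR, coding sequence, 3′ UTR, other exon, intron and intergenic. Class shares were tested against the share of bases with a two-sided exact binomial test. A gene was said to have a promoter peak where a summit lay within 1000 bp of any of its TSSs, so that neighbouring genes can share a peak.

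Replicate signals at an optimal peak were those of the strongest call overlapping it by at least 1 bp. Their Spearman correlation was tested with 100000 permutations. For the overlap of the replicates, the 5321 calls with the highest signal in each were compared, beside 100 random placements of the replicate 3 calls on the same arms. Gene lists (18, with 480 distinct genes) were tested against all other protein-coding genes with two-sided Fisher's exact tests. The lists were TORC1 and insulin signalling, autophagy, lysosome and V-ATPase, cytoplasmic ribosomal proteins, ribosome biogenesis and translation factors, mitochondrial respiratory chain and ATP synthase, glycolysis, energy storage and lipid metabolism, stress responses, bZIP transcription factors, embryonic patterning factors, cell cycle, and markers of neurons, glia, muscle, blood cells, fat body and germline. The member names Tor and nos each matched 2 genes and were assigned to mTor and nanos by locus. The names Ald and Pepck matched no single gene, and both had a listed counterpart. Whether each of 24 motifs occurred within 50 bp of a summit was compared with a window of the same size 500 bp to a randomly drawn side of the same summit, by an exact McNemar (binomial) test. All 6-mers, with reverse complements joined, were compared in the same way. Peak numbers per chromosome were tested against shares of bases, Y included, with exact binomial tests, and the median signal of promoter and distal peaks with 100000 permutations. Each family of tests was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05.

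The named genes were chosen by a rule: the 15 optimal peaks with the highest signal, with the nearest protein-coding TSS; in each list up to 4 members with the highest promoter signal, or all bound members where there were at most 5; REPTOR, REPTOR-BP, Thor, unk and InR in every case; and the motifs and 6-mers past the threshold with the largest ratios or smallest p. Lists, motifs, the other tests, this rule and the alternatives were set before the data were examined, apart from the few named below as added. The alternatives changed the TSS window (500 and 2000 bp), the summit window (25 and 100 bp), the control distance (1000 bp), the overlap rule, the build, the peak set (a stricter list of the 2660 peaks with the highest signal, or each replicate alone), the gene rule (gene body, protein-coding TSSs only) and the comparison genes (10000 draws matched on the number of TSSs, with 6 or more as 1 class). Matching on neighbouring TSSs, assigning a summit to the nearest gene alone, and a correlation over all calls were added after the data were seen. So were the tests of annotated classes other than promoters, and the comparisons of motifs between promoter and distal and between strong and weak peaks. The tests of explanations for the raised motifs and for chromosome 4 were also outside the first plan, and were made on results already known.

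The tests of motifs, 6-mers, gene lists, replicate correlation and overlap, median signal and chromosomes were tried on simulated data, and the matched lists, the permuted letters and the motif comparisons between sets of peaks were not. For the motif comparison, a site planted at 5% of 5318 random summits was recovered at 5.10 percentage points above the control windows, and 0 of 23 other motifs passed the threshold. For the gene lists, 5 lists raised to 70% among 13945 genes were recovered in 94.3% of their tests over 200 runs, while 1.33% of unchanged lists passed. The simulated genes were bound independently, while 60.0% of the bound genes in the data shared their strongest promoter peak with another gene. That rate of false calls therefore does not carry over to the data. For the 6-mers, both words inside the planted site passed, and so did 4 others. The random summits of the motif and 6-mer simulations had no built-in difference from their controls in annotated class or base composition. The real summits did differ, with a GC content of 39.0% against 43.5%, so the simulated false calls do not carry over to them. For the replicate correlation, a rho of 0.683 in 5321 pairs was recovered as 0.676. The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.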

Results

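The data were peak lists from ChIP-seq of GFP-tagged REPTOR, a bZIP transcription factor, in whole embryos 0 to 24 h old, in 2 biological replicates. Each sample was a pool of whole embryos, so the peaks were not assigned to a tissue. The optimal list held 5321 peaks on dm6 and 5304 on dm3. The dm6 peaks had a median width of 436 bp (109 to 808 bp) and a pooled signal from 77.9 to 2773, with a median of 125. The replicate lists held 30000 calls each, with signals from 10.6 to 1361 in replicate 1 and from 12.6 to 1403 in replicate 3. Read depth was not stated in the files.

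The strongest REPTOR peaks were the same in both replicates. The peak upstream of cbt, a zinc finger transcription factor gene, ranked 1 in each, and the peak at CG11050 ranked 4 in each. The peaks at CG14100 and at Ugalt, which encodes a UDP-galactose transporter, ranked 2 and 3 in replicate 1 and 3 and 2 in replicate 3. Of the 5321 optimal peaks, 5304 (99.7%) overlapped a call in each replicate, as did 20220 of all 30000 calls made on both. The optimal list was selected on both replicates, which sets this overlap high in advance. Across these 5304 peaks the replicate signals correlated with a Spearman rho of 0.74 (permutation p = 1e-05, the smallest that the permutations can give), where peaks are not independent replicates. In the strongest 1328 peaks rho was 0.78, and in the next groups of 1328, 1326 and 1322 it was -0.05, -0.32 and -0.31. The groups were cut by pooled signal, which itself lowers rho within each, and were not set in advance. Both replicates ranked 100% of the strongest group and 32.9% of the weakest among their first 5321 calls. The log2 ratio of replicate 1 to replicate 3 had a median of -0.04 and an SD of 0.48. It passed 2-fold at 241 peaks (4.54%), of which 102 were higher in replicate 1 and 139 in replicate 3. Among the 5321 strongest calls of each replicate, 78.0% (95% interval 76.9 to 79.1) of those in replicate 1 overlapped those in replicate 3, and 80.6% (79.5 to 81.7) the reverse. Random placement gave 3.14% on average and 3.95% at most.

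**Figure D1:**
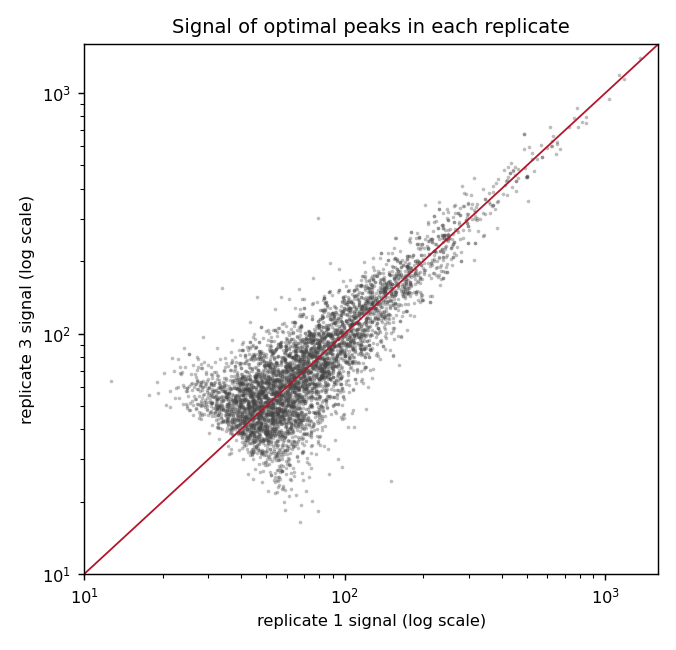
Signal of each optimal dm6 peak in replicate 1 (x axis) and replicate 3 (y axis), both in the caller's signal units on log scales, with 1 point per peak and a line of equal signal. The strongest peaks lie on the line, and the spread widens toward the weakest, with a Spearman rho of 0.74 over 5304 peaks.

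REPTOR peaks lay mostly at promoters. Of the summits, 3784 (71.1%, 95% interval 69.9 to 72.3) were within 1000 bp of a TSS, a class that made up 23.6% of bases (3.01-fold; the exact binomial p was under 1e-300). Introns held 1105 summits (20.8% against 36.2% of bases) and intergenic sequence 356 (6.69% against 25.02%). Coding sequence away from promoters held 7 summits (0.132% against 10.5% of bases, adjusted exact binomial p = 9.66e-241), and 3′ UTRs held 36 (0.677% against 3.71%). Summits in 5′ UTRs away from promoters numbered 11 and were 0.462 times their share of bases (adjusted exact binomial p = 0.00621). Non-coding exons, with 22 summits, did not pass (adjusted exact binomial p = 0.552). Each summit fell in a single class, so the high promoter share lowers the other classes against all bases in advance. These tests therefore cannot tell whether a class was low among distal summits, and shares of non-promoter bases were not tested. Among the other classes the ratio to the share of bases was lowest in coding sequence (0.0125), 3′ UTRs (0.182) and intergenic sequence (0.267). It was higher in introns (0.574) and non-coding exons (0.864). The median distance from a summit to the nearest protein-coding TSS was 229 bp, and 35.2% of summits were within 100 bp. Promoter peaks were slightly stronger than distal ones, with a median signal of 127 against 118 (difference 9.02, two-sided permutation p = 0.00012), and their interquartile ranges of 96.7 to 189 and 94.1 to 169 overlapped.

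**Figure D2:**
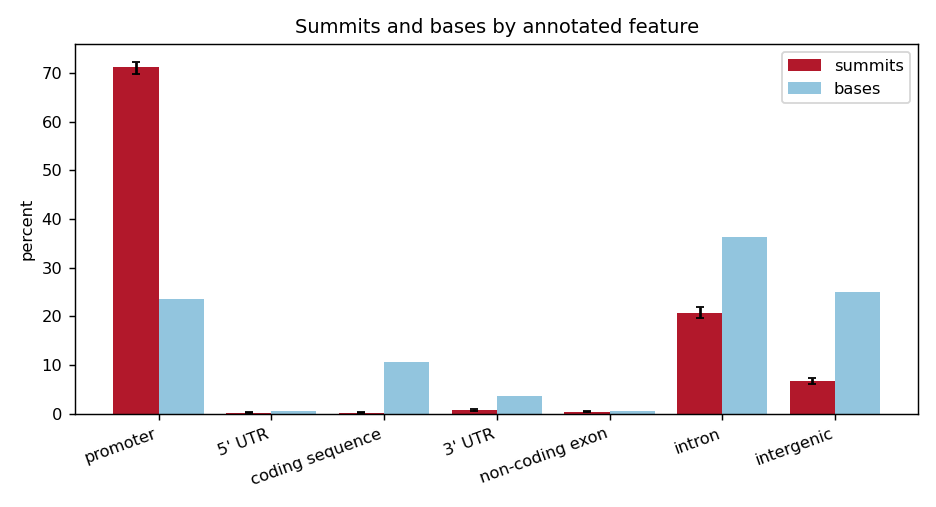
Share of 5321 optimal summits (red, with exact 95% intervals) and of bases (blue) in each annotated class, in percent. Promoters held 71.1% of summits and 23.6% of bases, and coding sequence 0.132% and 10.5%.

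The 15 strongest peaks lay near genes of varied function. The top peak (2L, 480581 to 481388, signal 2773) was in an intron of ush, which encodes a GATA cofactor, at -1391 bp (upstream) from the nearest protein-coding TSS, that of cbt. Peaks at the promoters of CG14100 (3L, 19590376 to 19590832) and Ugalt (X, 2703637 to 2704113) had signals of 2323 and 2302. The peak in an intron of CG11050 (2L, 6612449 to 6612941) had a signal of 1972. Promoter peaks followed at px, named for its wing vein phenotype (1640), Art3, an arginine methyltransferase gene (1639), and mRpL41, a mitochondrial ribosomal protein gene (1585). Lk6, which encodes a kinase of the translation factor eIF4E, had a promoter peak of 1573 in an intron (3R, 11760826 to 11761344). Chro, for the chromatin and spindle protein Chromator (1542), and ph-p, for a Polycomb group protein (1488), had promoter peaks, the former in the 5′ UTR. PNPase, for a mitochondrial RNA-degrading enzyme, had a peak of 1442 in its 5′ UTR, and larp, for an RNA-binding regulator of translation, had a peak of 1328 in an intron near its TSS. The remaining peaks of the set were near CG9663 (1291), CG4004 (1265, 5081 bp from the TSS of that gene and in a non-coding exon) and CG32772 (1262, intronic). The peak near CG4004 counted as a promoter peak, since it lay within 1000 bp of a TSS of a gene that is not protein-coding. All 15 ranked among the strongest 20 calls in both replicates.

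REPTOR itself carried some of the strongest peaks. Its best peak (3R, 24572431 to 24572863, signal 955, rank 33) lay 166 bp upstream of an internal REPTOR TSS and ranked 32 and 42 in replicates 1 and 3. In all, 13 optimal summits lay within 5000 bp of the gene, which spans 24557368 to 24582864 on the minus strand. This is also the gene from which the tagged transgene was made, and the number of copies of its sequence in the flies was not given. Extra copies therefore cannot be told apart from binding as a source of the signal there. REPTOR-BP, which encodes the bZIP partner of REPTOR, had a promoter peak with a signal of 221 (2L, 10264163 to 10264407, rank 938). Thor, which encodes a translation inhibitor held in check by TORC1, had a peak of 441 that began upstream of its TSS (2L, 3478248 to 3478633, rank 203), and 5 optimal summits lay within 5000 bp of that gene. The zinc finger gene unk had a peak of 503 (3R, 23156720 to 23157146, rank 146), whose summit was 968 bp inside the gene from its nearest TSS and was not counted with a 500 bp window. InR, the insulin receptor gene, had 3 promoter summits, the strongest with a signal of 324 (3R, 21618481 to 21618739, rank 408). Replicate ranks for these 4 peaks were 1071 and 938 at REPTOR-BP, 238 and 192 at Thor, 140 and 143 at unk, and 453 and 382 at InR.

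**Figure D3:**
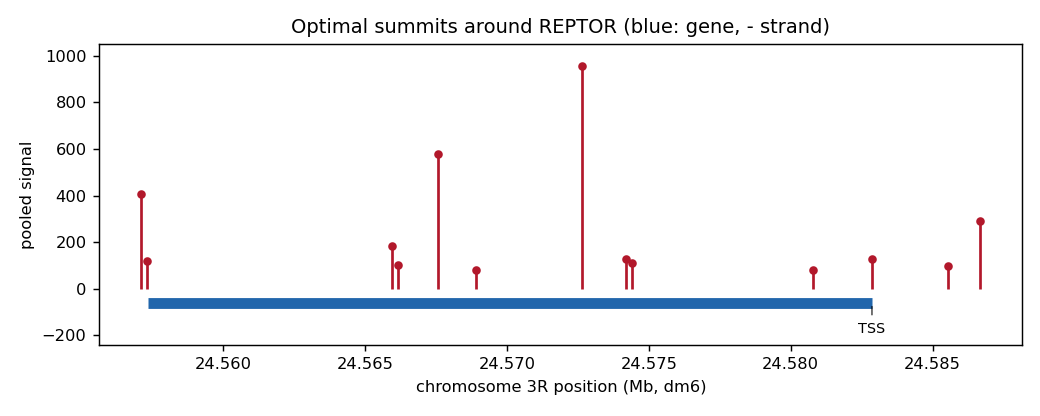
Pooled signal (y axis) of the 13 optimal summits within 5000 bp of REPTOR against dm6 position on 3R in Mb (x axis), with the gene as a blue bar and its outermost TSS marked. The strongest summit, with a signal of 955, lies inside the gene.

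Genes of TORC1 and insulin signalling had promoter peaks more often than other genes. In all, 4226 of 13945 protein-coding genes (30.3%) had a promoter peak, and 834 of them had more than 1 summit. Of the TORC1 and insulin list, 22 of 34 had a peak (64.7%, 95% interval 46.5 to 80.3; adjusted Fisher's exact p = 3.6e-04). The strongest after REPTOR were at Sesn, which encodes the TORC1 inhibitor sestrin (2R, 23713421 to 23713880, signal 706), alc, for the AMPK beta subunit (556), and unk. Of the 18 lists, 8 passed the threshold, each above the background, and some genes were in more than 1 of them. A peak was often shared: 2536 of the 4226 genes (60.0%) had a strongest promoter peak that was also the strongest of another gene.

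Ribosomal protein genes had the highest share of all lists. Peaks were at 75 of 86 cytoplasmic ribosomal protein genes (87.2%, 95% interval 78.3 to 93.4; adjusted Fisher's exact p = 7.67e-27), led by RpL7 (signal 785, 2L, 10200858 to 10201200), RpS27 (693), RpL22 (641) and RpL23A (622). Of the genes of ribosome biogenesis and translation factors, 12 of 18 had a peak (adjusted Fisher's exact p = 0.0047), among them eEF1alpha1 and eEF2, for elongation factors (275 and 198), Fib, for the nucleolar methyltransferase fibrillarin (170), and Nopp140, for a nucleolar protein (162). The adjusted Fisher's exact p for that list was 0.34 in the stricter peak list and 0.235 without replicate 1, in a range from 0.00151 to 0.34 over its alternatives.

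Genes for stress responses and energy storage were also bound. Of the unfolded protein, integrated and heat stress genes, 19 of 29 had a peak (65.5%, 95% interval 45.7 to 82.1; adjusted Fisher's exact p = 7.37e-04): Atf3, a stress-induced bZIP factor gene (signal 941, X, 1275246 to 1275729), the chaperone genes Hsp27 (454) and Hsp83 (355), and Ire1 (327), which encodes the endoplasmic reticulum stress sensor. The bZIP list had 12 of 19 (63.2%, adjusted Fisher's exact p = 0.00929), led by REPTOR, Atf3, Irbp18 (383) and CrebB (272). Of its bound genes, REPTOR and REPTOR-BP were also in the TORC1 list, and Atf3, Xbp1, cnc, CrebA, crc and maf-S in the stress list. The bZIP result is therefore not separate from the results of those lists. With each summit given to the nearest gene alone, Ire1 and Irbp18 had no promoter summit. Against lists with the same numbers of TSSs, the adjusted permutation p of the bZIP list was 0.0975, the highest in a range from 7.31e-05 over its alternatives. Energy storage and lipid genes had 17 of 26 (65.4%, adjusted Fisher's exact p = 0.00113): Treh, for trehalase (555), Lpin, for a phosphatidate phosphatase (475), bigmax, for the partner of the sugar sensor Mondo (458), and SREBP, a lipid synthesis regulator (242). Treh had no promoter summit with a 500 bp window or with each summit given to the nearest gene alone. Cell cycle and replication genes had 18 of 28 (64.3%, adjusted Fisher's exact p = 0.00112): Dp, for the partner of E2F (617), dpa and dup, for replication licensing proteins (310 and 266), and BubR1, for a mitotic checkpoint kinase (230); by nearest gene alone dup had none.

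The lysosome and V-ATPase list had 15 of 25 (60.0%, 95% interval 38.7 to 78.9; adjusted Fisher's exact p = 0.00872), led by the proton pump genes Vha14-1 (350), Vha100-2 (295), Vha36-1 (277) and Vha55 (264). Vha14-1, Vha100-2 and Vha36-1 were not the genes nearest to their peaks, Vha14-1 had no promoter summit with a 500 bp window, and with each summit given to the nearest gene alone the adjusted Fisher's exact p of the list was 0.381, the highest in a range from 1.29e-04 over its alternatives. Glycolysis, with 8 of 13 genes (61.5%, 31.6 to 86.1), did not pass (adjusted Fisher's exact p = 0.057), and its adjusted p ranged from 0.00647 to 0.472 over its alternatives. Its strongest members were Gapdh2 (657), Hex-A, for hexokinase (448), Pgk (297) and Ldh (260). Autophagy, with 10 of 24 genes (41.7%), also did not pass (adjusted Fisher's exact p = 0.319), and passed with a 2000 bp window (0.0197, in a range up to 0.98). Its strongest members were Atg6, the fly Beclin gene (417), Vps15 (241), Atg2 (218) and Atg4b (213, none by nearest gene alone). The mitochondrial respiratory chain, with 29 of 71 (40.8%, adjusted Fisher's exact p = 0.113), had its strongest peaks at ND-ASHI (384), ND-MWFE (359), ND-24 (264) and COX5A (253), of which ND-MWFE and COX5A had none by nearest gene alone.

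Genes of specific tissues and of embryonic patterning did not pass, and most of those lists lay below the background of 30.3%. Patterning factors had 5 of 35 (14.3%, 95% interval 4.81 to 30.3; adjusted Fisher's exact p = 0.0758): fkh (268), bcd (191), tin (119), dl (114) and en (101). Neuronal markers had 2 of 18 (11.1%, adjusted Fisher's exact p = 0.162), elav (491) and Syx1A (102). Blood cell and fat body markers each had 1 of 13 (7.69%, adjusted Fisher's exact p = 0.162), ush (130) and apolpp (86.5). Against lists with the same numbers of TSSs these 4 lists passed, with adjusted permutation p of 0.0149, 0.0115, 0.0491 and 0.0491, each the lowest of the alternatives of its list, which reached 0.72, 0.445, 0.736 and 0.441. Glial markers had 4 of 9 (moody 633, Gs2 335, nrv2 123, loco 101; adjusted Fisher's exact p = 0.526). Muscle markers had 5 of 15 (Msp300 547, sls 410, Mef2 162, Mlc1 138, Tm1 80.3; adjusted Fisher's exact p = 0.829) and germline markers 4 of 15 (nanos 189, tud 134, gcl 129, pum 95.8; adjusted Fisher's exact p = 1). By nearest gene alone gcl had no promoter summit, and with a 500 bp window Gs2, Mlc1 and loco had none. In the stricter list tin, dl, en, Syx1A, apolpp, nrv2, loco, Tm1 and pum had none, nor had Tm1 and apolpp without replicate 1 or en without replicate 3. The peak at en ranked 7199 in replicate 1 and 2020 in replicate 3, and that at ush 1095 and 5588.

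**Figure D4:**
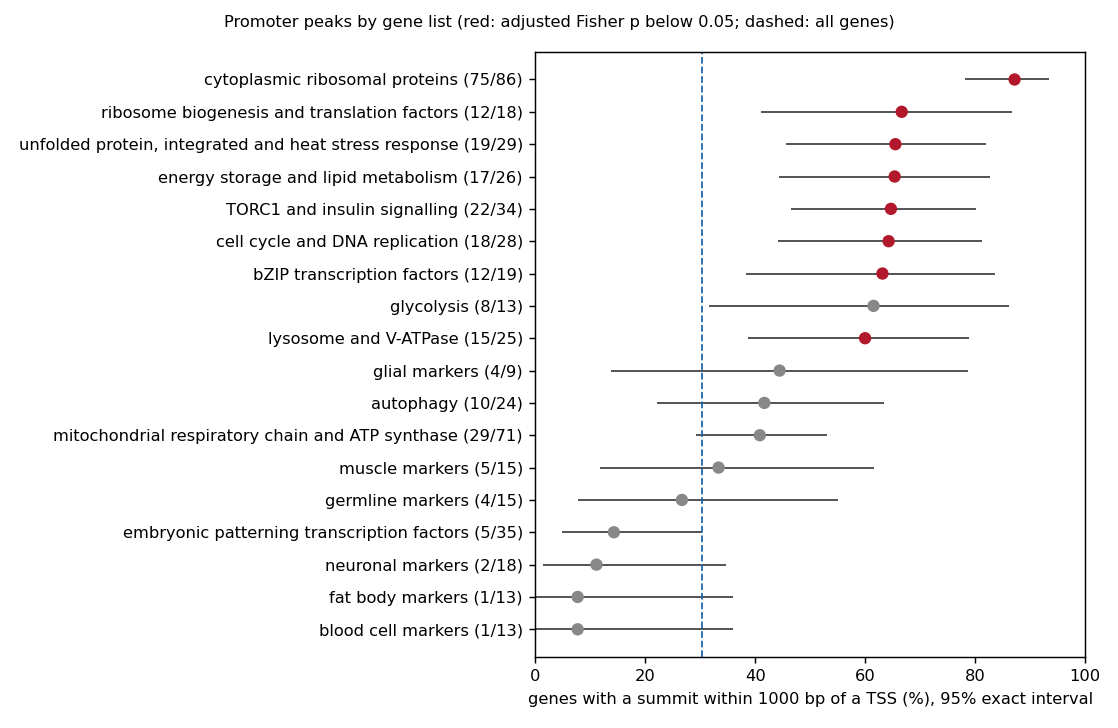
Share of the genes of each list with a summit within 1000 bp of a TSS (x axis, percent, exact 95% intervals), with bound and total members in parentheses. Red points passed the adjusted threshold, and the dashed line marks the 30.3% of all protein-coding genes. Cytoplasmic ribosomal proteins lie highest, at 87.2%.

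Sites of promoter and insulator proteins were raised at the summits, while sites of the CRE type, bound by many bZIP dimers, were not. The DNA replication-related element (DRE, TATCGATA), bound by the promoter factor DREF, occurred at 189 summits (3.55%, 95% interval 3.07 to 4.08) against 24 control windows (0.451%), a ratio of 7.88 (adjusted exact McNemar p = 1.33e-31). Motif 1 (GGTCACACT), the site of the promoter factor M1BP, occurred at 1.64% against 0.282% (ratio 5.8, adjusted exact McNemar p = 1.98e-12). The CTCF site (AGRTGGCGC), of an insulator protein, occurred at 1.43% against 0.282% (ratio 5.07, adjusted exact McNemar p = 2.41e-10). The FOXO site (GTAAACA), of the forkhead factor below insulin signalling, occurred at 3.76% against 2.12% (ratio 1.77, adjusted exact McNemar p = 3.95e-06). Unlike for DRE, Motif 1 and CTCF, base composition was not tested as a cause for this site. GC content was 39.0% at summits and 43.5% in the control windows. The CA repeat was lower at summits, at 1.99% against 3.25% (ratio 0.613, adjusted exact McNemar p = 2.37e-04). With controls 1000 bp away its adjusted exact McNemar p was 0.158, the highest in a range from 6.07e-08 over its alternatives. The CRE palindrome TGACGTCA was found at 12 summits and 17 control windows (adjusted exact McNemar p = 0.647). The CRE half-site TGACGT was found at 123 and 144 (adjusted exact McNemar p = 0.424), and the AP-1 site at 60 and 56 (adjusted exact McNemar p = 0.923). The other 16 motifs did not pass.

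**Figure D5:**
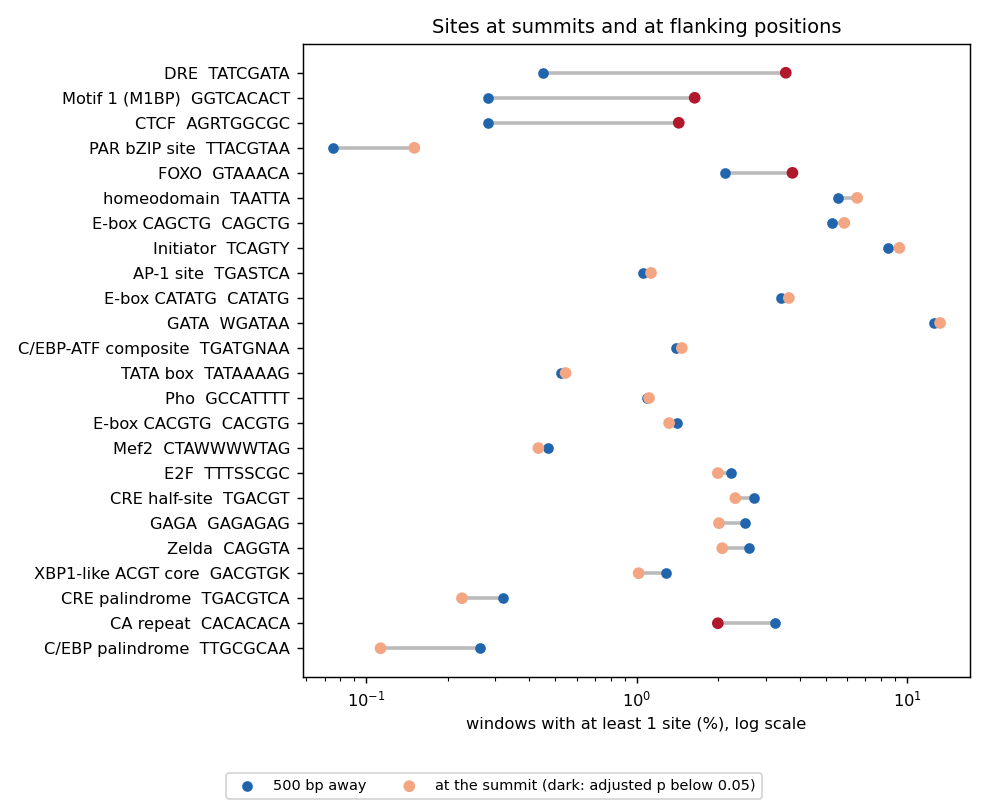
Share of windows with at least 1 site, in percent on a log scale, at 5321 summits (red or orange) and 500 bp away (blue), for 24 motifs ordered by ratio. Dark red marks the 5 motifs past the adjusted threshold, from DRE at 3.55% against 0.451% to the CA repeat at 1.99% against 3.25%.

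DRE and Motif 1 belonged to promoter peaks. DRE was present at 4.84% of promoter and 0.39% of distal summits (adjusted Fisher's exact p = 3.13e-19), and Motif 1 at 2.25% and 0.13% (adjusted Fisher's exact p = 1.07e-09). At distal summits alone neither passed against the controls (adjusted exact McNemar p = 0.838 and 1, each the highest of its alternatives), and the CRE half-site was below them, at 1.43% against 3.12% (adjusted exact McNemar p = 0.0186, the lowest of its alternatives, which reached 1). The CTCF site went the other way, at 1.14% of promoter and 2.15% of distal summits (adjusted Fisher's exact p = 0.0241). The E-box CAGCTG was more frequent at promoter summits (6.98% against 3.06%, adjusted Fisher's exact p = 5.6e-08), as was the CRE half-site (2.67% against 1.43%, adjusted Fisher's exact p = 0.0241). The GATA site (11.9% against 16.5%, adjusted Fisher's exact p = 7.01e-05) and the E-box CATATG (3.09% against 5.01%, adjusted Fisher's exact p = 0.00567) were more frequent at distal summits. None of the 24 motifs differed between the 1330 strongest and the 1330 weakest peaks at an adjusted Fisher's exact p under 0.05. The lowest unadjusted values were 0.00638 for the ACGT core of the XBP1 type and 0.02 for the homeodomain site, and 4 motifs were under 0.05 unadjusted.

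Of all 6-mers, 407 were more frequent at summits than in the control windows and 609 less frequent. The former were led by CGATAG, which shares its first 5 bases with the DRE, at 9.38% against 2.44% of windows (log2 ratio 1.94), and by the parts of the DRE TATCGA at 12.2% against 4.19% (1.54) and ATCGAT at 9.34% against 3.38% (1.46). ACACTG was at 10.4% against 3.87% (1.42), and AAAATA, with A and T only, at 29.2% against 18.5% (0.66). The latter were led by CTCCTC at 1.37% against 6.43% (-2.22), GGAGGA at 1.17% against 5.6% (-2.26), AGGAGG at 0.977% against 4.81% (-2.29), CCAGGA at 0.827% against 4.17% (-2.32) and AGGAGC at 1.54% against 5.62% (-1.86). The adjusted exact McNemar p of these 10 words lay between 1.21e-50 and 3.55e-28. At distal summits alone, CGATAG, TATCGA and ATCGAT did not pass. GC content averaged 39.0% at summits and 43.5% in the control windows. The control windows were not matched to the summits on annotated class, so a word can differ because of where the controls lie.

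REPTOR peaks were spread over the large arms and thin on chromosome 4. The arms 2L, 2R, 3L, 3R and X held 957, 1027, 1039, 1304 and 970 peaks, or 37.1 to 41.3 per Mb, and none of them passed against its share of bases (the lowest adjusted exact binomial p was 0.0812, for X). Chromosome 4 held 24 peaks, or 18.03 per Mb, which was 0.464 times its share of bases (0.451%, 95% interval 0.289 to 0.67, against 0.971%; adjusted exact binomial p = 8.72e-05). Among the strongest 5321 calls of a single replicate, 2R passed in replicate 3 (1054 calls, adjusted exact binomial p = 0.0255) and 2L in replicate 1 (982 calls, adjusted exact binomial p = 0.0297), and the values for these arms reached 0.671 and 0.255 over the alternatives. The shares of bases in these tests included Y, with 2.49% of bases and 0 peaks, which lowers the expected share of every other arm. The passes of 2R and 2L therefore cannot be told apart from an effect of counting Y. No call was named as lying on Y in any of the 8 lists. Calls on heterochromatic sequences of dm3 were counted apart, below. The exact 95% upper bound for 0 of 5321 peaks was 0.0693%. Whether reads on Y were kept for calling was not given, so this bound does not speak to binding there. The 24 peaks on chromosome 4 include that at apolpp, a lipoprotein gene.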

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

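Both counts in this part were tests chosen only after the data were seen. Of the calls made on both replicates together, 3070 had a −log10 q above 2 and lay below the threshold of the optimal list, outside the peaks on which the report's class, gene and motif results rest. The deposited list was filled to 30000 lines with background calls, so their number alone does not show binding. These calls had signals from 54.8 to 77.9, and 98.0% of them overlapped a call in each replicate, against 55.1% of the 21609 remaining calls; all were called on the reads of those replicates, so overlap was favoured in advance. Their summits were within 1000 bp of a TSS in 59.9% (exact 95% interval 58.2 to 61.7), against 71.1% in the optimal list and 41.0% among the remaining calls. They would add a promoter call at 1367 genes beyond the 4226 with an optimal promoter peak.

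On dm3, 50 of the calls made on both replicates lay on sequences named as heterochromatic or unplaced, and the dm6 lists did not hold these names. Whether calls on the dm6 arms cover the same sequences was not examined. The number of 50 too comes from a list that holds background calls and does not show binding. The lists of replicates 1 and 3 held 71 and 59 calls off the main arms, of which 2 in replicate 1 were on the mitochondrial genome. The strongest of the 50 ranked 4900, and 1 of them was in the optimal dm3 list. No gene was assigned to these calls, since no dm3 annotation was used here.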

How the results depend on the processing

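A correlation over all calls, the assignment of summits to the nearest gene alone and the lists matched on neighbouring TSSs were chosen after the data were seen; the other alternatives were set before. Of 55 values of the main results under their alternatives, 46 stayed on the same side of the threshold or within the limits set for them, and 9 moved. No paired analysis was possible because the series held a single group. Taking the strongest calls made on both replicates, in the number of the optimal list, gave exactly the optimal list, so that comparison was void.

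The stricter list held 2660 peaks by construction, and 2443 genes then had a promoter peak in place of 4226. The overlap of replicate 1 with replicate 3 was 70.1% with a 50% reciprocal overlap, 70.6% with summits within 100 bp, 79.8% for the strongest 2660 calls and 74.5% for 2 times as many calls as the optimal list, against 78.0%. The first 2 rules ask for closer positions and lower it by construction, and the cause of the other 2 changes was not tested. Enriched motifs numbered 8 with a summit window of 100 bp and 2 (CTCF and FOXO) at distal peaks only, against 4, and all 4 were among the 8; the cause was not tested. Enriched 6-mers numbered 131 at distal peaks, a smaller set of 1537, against 407. The 6-mer ATCGAT had a log2 ratio of -0.49 at distal peaks (adjusted exact McNemar p = 0.369, in a range from 1.26e-40) against 1.46 overall; the cause was not tested.

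The Spearman rho lay between 0.71 (summits within 100 bp) and 0.76 over its other alternatives, and Pearson's r on log2 signal was 0.83. The promoter share was 62.1% and 80.4% with windows of 500 and 2000 bp, which cover 13.6% and 37.8% of bases, and 70.6% to 70.9% with a replicate left out. Promoter against distal signal kept its direction, with permutation p of at most 0.001. Without a replicate, genes with a promoter peak numbered 4126 to 4236, lists past the threshold 7 to 9 and enriched motifs 4, all 4 shared with the main set. Of 8 lists past the threshold, 7 or 8 also passed under each alternative, and lists matched on numbers of TSSs added 4 lower ones. Of 874 values for single lists, motifs, arms and genes, 813 kept their call, 38 lost it, 22 gained it and 1 reversed. Of 67 named genes, 9 had no promoter summit in the stricter list, 6 with the 500 bp window, 11 by nearest gene and 2 and 1 without replicates 1 and 3. Read depth was unknown, so no limit from depth could be set.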

Other observations

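The gene families, RNA and pseudogene classes and REPTOR neighbourhood of this part, the share of calls on chromosome 4 and the comparison of the TORC1 list with other lists were tests chosen only after the results were seen. The families were also revised after a first run: of 15, the patterns for cuticle and chorion genes took in wrong genes and were corrected, and histones and a set of TORC1 regulators were dropped because their patterns took in unrelated genes, which left 13. Mitochondrial ribosomal protein genes had promoter peaks at 42 of 73 (57.5%, exact 95% interval 45.4 to 69.0; adjusted Fisher's exact p = 6.99e-06 over 13 families), led by mRpS10 (signal 1639, shared with Art3), mRpL41 (1585) and mRpS23 (1211). Translation initiation factors had 23 of 44 (52.3%, adjusted Fisher's exact p = 0.00689), with eIF2Bbeta, which shares the peak of 2302 with Ugalt, and eIF6 (1065) in front. Proteasome subunits (18 of 48, 37.5%) and tRNA synthetases (15 of 33, 45.5%) did not pass (adjusted Fisher's exact p = 0.357 and 0.139), nor did CCT chaperonin subunits (5 of 8), Sm and snRNP proteins (3 of 8) and Tim and Tom import proteins (5 of 15; adjusted Fisher's exact p = 0.112, 0.764 and 0.783).

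Receptor, cuticle and cytochrome P450 genes had promoter peaks less often than other genes. Peaks were at 4 of 179 odorant, gustatory and ionotropic receptor genes (2.23%, adjusted Fisher's exact p = 1.83e-21): Ir60e, Gr97a, Gr63a and Or88a. They were at 1 of 70 Cpr cuticle genes (1.43%, Cpr73D; adjusted Fisher's exact p = 3.4e-09) and at 5 of 85 cytochrome P450 genes (5.88%, adjusted Fisher's exact p = 1.68e-07), of which Cyp6u1 (358) was the strongest. None of 8 homeotic genes of the homeobox clusters had a promoter peak (exact upper bound 36.9%, adjusted Fisher's exact p = 0.167), and Jonah protease genes (1 of 16) and chorion and vitelline membrane genes (0 of 5) did not pass either (adjusted Fisher's exact p = 0.112 and 0.392). Among other gene classes, 40 of 290 tRNA genes (13.8%) and 428 of 3261 other non-coding RNA genes (13.1%) had a summit within 1000 bp, below the 30.3% of protein-coding genes (adjusted Fisher's exact p = 1.9e-10 and 1.31e-97), as were 0 of 99 rRNA genes and 12 of 268 pseudogenes (adjusted Fisher's exact p = 8.55e-16 and 1.56e-25). The 10 of 32 snRNA genes (31.2%) and 69 of 269 snoRNA genes (25.7%) did not pass (adjusted Fisher's exact p = 1 and 0.129). Neither these classes nor the families were matched on numbers of TSSs per gene, and the tests take genes as independent, also where they lie close together. How well reads map to repeated genes was not known, so the low shares, that of rRNA genes included, do not show absent binding.

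The REPTOR locus held 13 optimal summits within 5000 bp of the gene and 30 of the 30000 calls. Among 381 protein-coding genes of similar length (a ratio of at least 0.8 between the shorter and the longer), the median was 1 optimal summit and 9 calls, and 1 gene had as many optimal summits and 7 as many calls. Some of the 13 peaks overlap each other, so they are not 13 separate regions. Merging overlapping peaks over the whole optimal list left 4993 of 5321. The copies of this locus in the flies were not given, and extra copies can raise calls there without binding, so the excess does not show binding.

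Sites for DREF, M1BP and CTCF were raised at summits that showed no rise of the CRE. The tests below were made for these 3 motifs when their rise in the same data was already known. Base composition as the whole cause is argued against for DRE and CTCF: their log2 ratios lay at the 100th and 97.5th percentile of 200 versions of each site with permuted letters. For Motif 1, at percentile 95, it cannot be told apart: its log2 ratio of 2.50 was above the 95th percentile of 2.35, which was to count against base composition, but the permuted versions occurred at a median of only 4 windows, and those of CTCF, read as sufficient, at 7. Sites equally common at all annotated promoters are argued against for all 3. Genes with a promoter peak carried the site within 200 bp of their outermost TSS more often than other genes. The odds ratios were 2.59 (95% interval 2.3 to 2.91) for DRE, 2.3 (1.99 to 2.65) for Motif 1 and 1.6 (1.09 to 2.34, Fisher's exact p = 0.013) for CTCF. These windows can include the summits themselves, and neighbouring genes can share a peak. Which promoters were active was not known, so sites common to active promoters cannot be told apart. No biological explanation was tested, since the series held a single group.

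Chromosome 4 held fewer peaks than its share of bases. Poor mapping cannot be told apart: 1.37% (exact 95% interval 1.24 to 1.51) of the 30000 calls lay there, above its 0.996% of the bases of the 6 arms, which was at first to count against it, but that list holds background, only 56 of the 8391 calls with a −log10 q above 2 (0.667%, 0.505 to 0.866) lay there, and the median signal was 29.1 against 34.8 elsewhere. Fewer promoters stays open: chromosome 4 had 60.1 protein-coding genes per Mb against 105 elsewhere, and 16 of its 80 genes had a promoter peak against 30.4% of others, an odds ratio of 0.573 (95% interval 0.309 to 1.0; Fisher's exact p = 0.0503). An interval that included 1 was at first to count for this explanation, and that reading was dropped after the value was seen, because with 80 genes an equal share of bound promoters and a lower one cannot be told apart. No biological explanation was tested.

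The TORC1 and insulin list had promoter peaks at 64.7% of its genes. More start sites per gene are argued against, since the list lay above lists matched on the number of TSSs (log2 ratio of its bound members to the number expected 0.86, two-sided permutation p = 0.001), and so is closeness to the start sites of other genes (log2 ratio 1.03, two-sided permutation p = 0.0002, the smallest that 10000 draws can give). What stays open is that other broadly used functions are bound as often: 176 of 270 genes of the ribosome, translation, lysosome, respiratory chain, glycolysis, stress and cell cycle lists had a peak (65.2%, exact 95% interval 59.2 to 70.9; Fisher's exact p = 1), and 101 of 184 without the ribosomal proteins (54.9%, 47.4 to 62.2; Fisher's exact p = 0.348). Those 7 lists were picked when their shares were already known and ran from 40.8% (respiratory chain) to 87.2% (ribosomal proteins), so no common level is shown, and the raised share may or may not be particular to this pathway. No biological explanation was tested, since the series held no other factor or condition.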
